A study of Homo sapiens with 6 samples.

How the data were processed

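The series holds 6 arrays of HTR8/SVneo trophoblast cells, 3 cultures given vehicle and 3 given 65 µM coumestrol, all harvested after 24 h. Per the labels' protocols, total RNA was extracted with a phenol-based kit and biotinylated cRNA was hybridised to Affymetrix arrays; the culture density at treatment is described in different words in different labels. The deposited values are log2 RMA values, 1 per probe set and array, and per the submitters' processing notes they were made with RMA and Partek 7.0. RMA corrects background, quantile-normalizes the arrays and summarises probes by median polish; filters and the build of the array's annotation are not given in the sources used here, so no coordinates are reported. The values ran from 2.84 to 14.2, in the range of log2 RMA output. The array medians were 6.85, 6.87 and 6.85 for vehicle and 6.84, 6.85 and 6.83 for coumestrol. Arrays have no read depth, and their number limits the precision.

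Gene names came from the platform annotation. Of 21448 probe sets, 17709 had 1 gene symbol, 0 had several and 3739 are unnamed here. All 17709 symbols matched the gene table of the GRCh38.p14 assembly by gene identifier and 0 needed an update; that table was also used for gene spans and for which genes neighbour each other. The named probe sets stood for 17687 genes, 20 of them with more than 1 probe set; for these the probe set with the highest mean over the 6 arrays stood for the gene in list tests. Values identical to those of another probe set on the same arrays were found for 78 probe sets. No array duplicated another, since at most 4 probe sets agreed exactly between any 2 arrays.

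Coumestrol and vehicle were compared with limma 3.58.1 in R 4.3.3, by a linear model on the log2 values of all probe sets, empirical Bayes moderation with an intensity trend (10.3 prior degrees of freedom) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Fold changes are coumestrol minus vehicle on the log2 scale, and folds are their antilogs. The median standard error of a log2 fold change was 0.136. Tests are two-sided unless stated. Gene lists, 34 in number, were tested on 1 probe set per gene by camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Counts adjusted over the list alone use the same p-values adjusted within the list.

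The design, the lists, the alternatives except those named as added, and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among probe sets with 1 symbol that passed the threshold with no overlap between groups. From each list it took up to 3 called members with the largest changes, and the called member with the largest change against the list's direction, or, where none was called, the member with the smallest p. It always took ESR1, ESR2, GPER1, AHR, CYP1A1, CYP1B1, HLA-G, KRT7, VIM, MKI67, CDKN1A, HMOX1, VEGFA, MMP2 and MMP9. Genes outside the rule are named as such.

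Replicate numbers are shared by the groups, but the labels do not say that they pair the cultures, so no block was used in the comparison. The alternatives were other variance moderation, filters on dim probe sets, further normalization, array weights, the replicate number as a block, probe sets with 1 symbol only, a threshold of 0.01, the mean of a gene's probe sets in list tests, and leaving out each array. Cyclic loess and counting identical probe sets once were added after the data were seen.

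The fit was tested on simulated data for the comparison of coumestrol with vehicle, on 21448 probe sets of which 200 were changed. It recovered 30% of those changed by 0.5 on the log2 scale and 95% of those changed by 1, with 7 false calls, and made 0 calls when nothing was changed. Far fewer probe sets were changed than the 2302 called in the real data. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the sensitivity in the real data. The list test, on 17687 simulated genes with 2 lists moved by 0.25, called both in the right direction and 0 others. The simulated genes were drawn independently, so this does not test lists whose genes are correlated. The simulated arrays also held no array that stood apart and no drift of the change with intensity. Random lists for comparison were drawn 10000 times from bins of mean intensity, and where stated of gene span. Their genes were drawn independently, so their ranges do not count correlation between a list's genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.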

Results

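Coumestrol is a plant estrogen found in clover, alfalfa and other legumes, and HTR8/SVneo is an immortalised human trophoblast line from early placenta that is used to study placental invasion. The question, from the series title and design text, was how gene expression in these cells changes after coumestrol. RNA from 3 cultures treated with vehicle and 3 treated with 65 µM coumestrol for 24 h was measured on Affymetrix arrays, 1 array per culture. The deposited log2 values covered 21448 probe sets, of which 17709 carried 1 gene symbol. Array medians lay between 6.83 and 6.87, and the SD of an array's values ran from 2.02 in vehicle replicate 2 to 2.14 in coumestrol replicate 2. The interquartile range was 3.032, 2.873 and 3.025 for vehicle and 3.101, 3.152 and 3.178 for coumestrol, so it parted the groups. The leading principal component held 50% of the variance and parted the groups, with scores of 8.47, 32.8 and 15.9 for vehicle and -12.5, -21.8 and -22.7 for coumestrol. Vehicle replicate 2 stood farthest out. With 3 arrays per group, the number of arrays limited the precision. The p-values rest on the spread between cultures labelled as biological replicates, moderated towards that of probe sets of like intensity.

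Coumestrol changed 2302 probe sets (10.7%), with 1616 higher and 686 lower, and the shifts were mostly small. The median size of a change was 0.50 on the log2 scale (1.42-fold), and 76 probe sets changed by at least 2-fold, 35 upward and 41 downward. The largest rises among named genes were in B3GNT2 (Entrez gene 10678), an enzyme that extends poly-N-acetyllactosamine chains on glycoproteins, from 8.14 ± 0.16 to 9.53 ± 0.12 (SD, n = 3 each; 2.62-fold), and in ANKRD13C (2.51-fold), ZNF567 (2.44-fold), BAAT (2.43-fold), LINS1 (2.40-fold) and FAM135A (2.33-fold). BAAT conjugates bile acids and fatty acids to amino acids. GRAMD1C, ELOVL4, ZNF302, RNF19A, KIAA0232 and TERF2IP rose by 2.12-fold to 2.20-fold; ELOVL4 elongates very long fatty acids and TERF2IP encodes the telomere protein RAP1. HSF5 (Entrez gene 124535), a heat shock factor of male germ cells, fell from 8.29 ± 0.09 to 6.52 ± 0.26 (3.43-fold lower), and the testis calreticulin CALR3 fell from 8.64 ± 0.11 to 6.87 ± 0.24 (3.41-fold lower). Of the 12 largest falls, 7 were in USP17L genes, near-identical deubiquitinase copies whose probe sets cannot be assumed to read separate genes; USP17L22 fell by 1.60 and USP17L15 by 1.35. ASB14 was 3.02-fold lower, the endothelial adhesion gene PECAM1 2.65-fold lower and KIAA0319 2.56-fold lower. The limma adjusted p of these 24 genes ran from 6.12e-06 for B3GNT2 and CALR3 to 0.00148 for KIAA0232, and the vehicle and coumestrol values of each did not overlap. ERRFI1, which encodes a feedback inhibitor of the EGF receptor and is named here after its values were seen, rose from 11.90 ± 0.02 to 12.94 ± 0.03 (limma adjusted p = 3.94e-08).

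**Figure D1:**
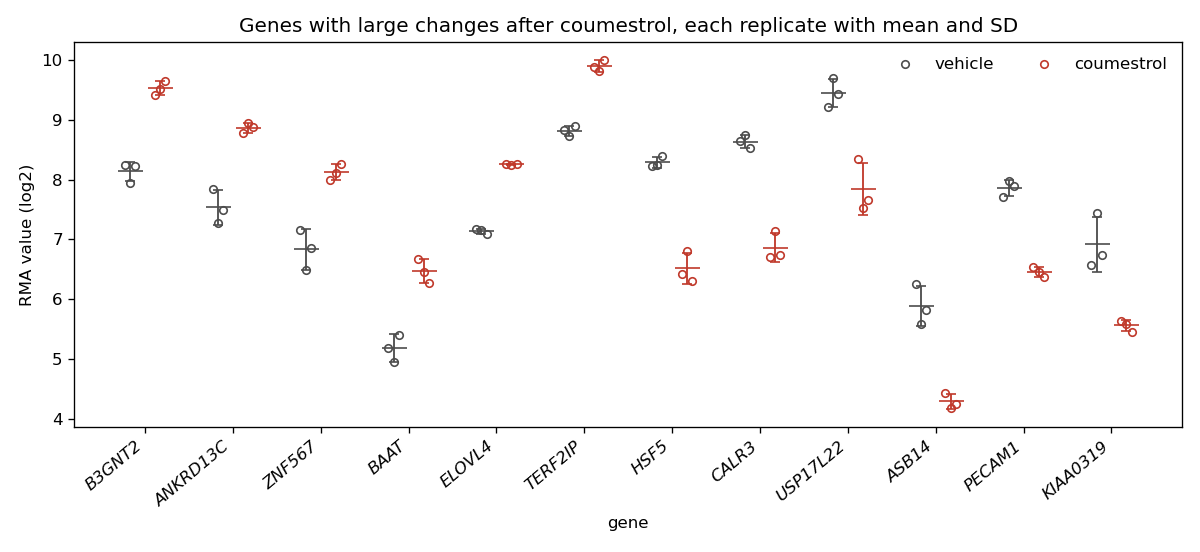
RMA values (log2, vertical axis) of 12 named genes with large changes, with open circles for the 3 vehicle and 3 coumestrol replicates, horizontal bars for means and whiskers for the SD. In each gene the coumestrol circles lie apart from the vehicle circles, as in HSF5, with means of 8.29 and 6.52.

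Of all probe sets, 6267 (29.2%, against 10% by chance) had vehicle and coumestrol values that did not overlap, as had 2274 of the 2302 called, and 5365 probe sets had an unadjusted p under 0.05. The share of calls that were higher was 70.2%, but 58.3% after another quantile normalization, 60.8% after cyclic loess and 53.8% with ribosomal protein genes as the reference. The count of calls fell to 1098 without coumestrol replicate 3 and 1459 without coumestrol replicate 2, to 1313 with a variance prior that ignored intensity, and to 184 with no moderation of the variance. Without coumestrol replicate 3 there were 859 higher and 239 lower calls, lower calls numbered 366 without coumestrol replicate 2 and 385 without vehicle replicate 3, and 115 probe sets changed by at least 2-fold without vehicle replicate 1. An exact two-sided permutation test of 3 against 3 cannot go below 0.1.

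Genes of the G2 phase and mitosis had the highest median change of the gene groups fixed in advance. Of 36 measured, 15 rose and none fell (22 rose when adjusted over the list alone), 35 had a positive change, and the median log2 change was 0.25. Among them were the spindle checkpoint kinase TTK (1.95-fold), the kinetochore gene NUF2 (1.90-fold) and CDK1 (1.71-fold), the kinase that drives entry into mitosis. Limma's camera gave the list an adjusted p of 1.06e-09 with a preset correlation, and adjusted p = 0.602 with an estimated correlation. Of 36 G1/S and DNA replication genes, 8 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.0551); the cyclins CCNE1 and CCNE2 and the histone mRNA binding gene SLBP rose by 1.81-fold, 1.78-fold and 1.78-fold, while the replication helicase gene MCM5 fell by 0.35. The proliferation marker MKI67 was at 10.07 ± 0.03 with vehicle and 10.16 ± 0.01 with coumestrol (limma adjusted p = 0.381). Homologous recombination and Fanconi anaemia genes numbered 23, with 4 higher (5 adjusted over the list alone; camera adjusted p = 0.0854), among them FANCB, EXO1 and BLM. Core and linker histone genes numbered 22, with 4 higher by either adjustment (4 adjusted over the list alone; camera adjusted p = 0.126), among them H1-2 and H3C8. The topoisomerase gene TOP2A rose 1.25-fold.

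Targets of p53 were higher as a group, with 8 of 23 raised and none lower (11 higher and 1 lower adjusted over the list alone) and a median of 0.16. TIGAR, which limits glycolysis, rose 1.92-fold, the BH3-only death gene PMAIP1 1.67-fold, the ribonucleotide reductase subunit RRM2B 1.58-fold and the cell cycle inhibitor CDKN1A 1.28-fold. The camera adjusted p of the p53 list was 0.00626 with the preset correlation, and adjusted p = 0.449 with an estimated correlation; without the dimmest 30% of probe sets it was 0.054, and without the dimmest 50% it was 0.133. Of 26 apoptosis and BCL2 family genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.196): the apoptosome gene APAF1 rose by 0.64, the death receptor TNFRSF10B by 0.40, and the survival gene BCL2L1 fell by 0.40.

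Several protein-folding and stress genes rose. Of 18 endoplasmic reticulum chaperone and unfolded protein response genes, 6 rose and none fell (6 adjusted over the list alone), including HERPUD1 (2.02-fold), which takes part in degradation of misfolded proteins, DNAJB9 (1.66-fold) and the chaperone HSPA5 (1.53-fold). The camera adjusted p was 0.00327 with the preset correlation, and adjusted p = 0.602 with an estimated correlation; without the dimmest 50% it was 0.0801, and the list's median of 0.13 lay within the central 95% range of random lists of like intensity (-0.092 to 0.149). Of 15 cytosolic heat shock genes, 5 rose and 2 fell (8 and 2 adjusted over the list alone), with DNAJB1 up 1.93-fold, HSPA1A up 1.33-fold and the small chaperone HSPB1 falling by 0.22. The heat shock list had a camera adjusted p of 0.0382, and adjusted p = 0.616 with an estimated correlation. It was 0.0988 and 0.0557 without vehicle replicates 2 and 3, and 0.0962 and 0.0524 without coumestrol replicates 2 and 3. It was 0.121 and 0.248 without the dimmest 30% and 50%, 0.133 after another quantile normalization and 0.168 after cyclic loess. With the replicate number as a block it was 0.0556. Of 28 genes of the ATF4 stress response, 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0756), including SESN2 (1.54-fold), DDIT4 and the serine synthesis gene PSAT1, with the mitochondrial SHMT2 falling by 0.27. Of 24 autophagy and lysosome genes, 6 rose and 1 fell (9 and 1 adjusted over the list alone): the autophagy kinase ULK1, ATG14 and MAP1LC3B rose by 0.56, 0.56 and 0.54, and the cargo receptor SQSTM1 fell by 0.24. That list had a camera adjusted p of 0.00626, and adjusted p = 0.602 with an estimated correlation; it was 0.10 after another quantile normalization, 0.0979 after cyclic loess, and 0.0565 and 0.14 without the dimmest 30% and 50%.

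Among antioxidant and xenobiotic genes, single members moved. Of 23 NRF2 target genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.183), with PGD up 1.65-fold, the glutathione synthesis gene GCLC up 1.62-fold, the heme oxygenase HMOX1 up 1.58-fold and the transporter ABCC3 falling by 0.68. The aryl hydrocarbon receptor AHR rose from 12.01 ± 0.07 to 12.49 ± 0.07, and of its 7 measured targets 1 rose, TIPARP, by 1.74-fold (1 adjusted over the list alone; camera adjusted p = 0.868). CYP1A1 was at 4.82 ± 0.29 with vehicle and 4.67 ± 0.22 with coumestrol (limma adjusted p = 0.64), and CYP1B1 at 5.42 ± 0.03 and 5.20 ± 0.28 (limma adjusted p = 0.452). Both genes lay below the array medians, and dim probe sets were called less often than bright ones. The zinc exporter SLC30A1 rose 1.79-fold and the metallothionein MT1E 1.46-fold, which were the 2 of 10 metallothionein and zinc transport genes that rose (2 adjusted over the list alone; camera adjusted p = 0.302).

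Of 20 genes known to be induced by estrogen in other cells, 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.92). The nuclear receptor corepressor NRIP1 rose 1.78-fold, XBP1 1.37-fold and RARA 1.28-fold, while MYC fell by 0.27. NRIP1 kept its call at 0.05 under each alternative that moderated the variance, while XBP1, RARA and MYC lost theirs without coumestrol replicate 3 (limma adjusted p = 0.171, 0.0649 and 0.0753) and with a variance prior that ignored intensity. In all, XBP1 lost its call under 6 such alternatives, and RARA and MYC under 2 each. The estrogen receptor genes did not pass the test: ESR1 was at 6.28 ± 0.28 with vehicle and 6.18 ± 0.12 with coumestrol (limma adjusted p = 0.771), ESR2 at 5.11 ± 0.40 and 4.70 ± 0.06 (0.184), and GPER1 at 5.03 ± 0.14 and 4.71 ± 0.04 (0.172). These levels lay below the array medians of 6.83 to 6.87. Dim probe sets were called less often than bright ones, so the missing calls do not show that these genes were unchanged. The list that joins these receptors with proteins reported to bind coumestrol had 2 of 11 genes higher, AHR and TOP2A (2 adjusted over the list alone; camera adjusted p = 0.765).

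**Figure D2:**
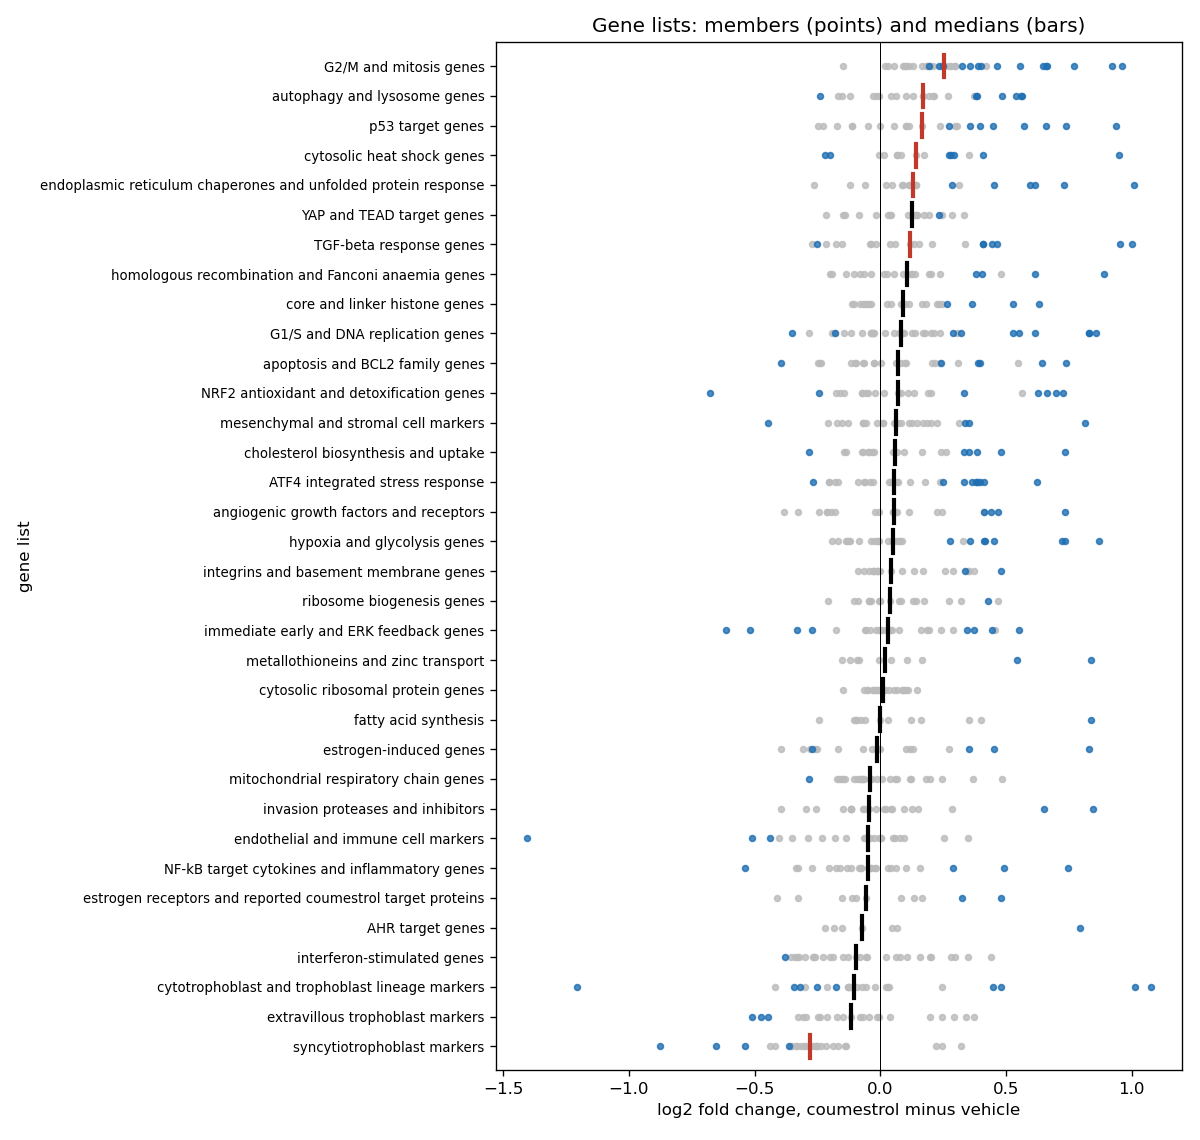
Log2 fold change (coumestrol minus vehicle, horizontal axis) of the measured members of 34 gene lists, with blue points for members past the test, grey points for the others, and bars for list medians, red where camera's preset test passed. Medians ran from -0.28 for syncytiotrophoblast markers to 0.25 for G2/M and mitosis genes.

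Syncytiotrophoblast markers, which mark the fused hormone-secreting layer of the placenta, were lower as a group. Of 28 measured, 4 fell and none rose (6 fell adjusted over the list alone), 25 had a negative change, and the median was -0.28. The list holds several CGB and several PSG genes. Whether their probe sets read separate transcripts was not tested, so its members may not count separately. The fusogen ERVW-1 (syncytin) was 1.84-fold lower, the galectin LGALS13 1.58-fold lower and CGA, the shared alpha subunit of chorionic gonadotropin, 1.45-fold lower. LGALS13 lost its call without coumestrol replicate 2 or 3 (limma adjusted p = 0.0642 and 0.0831), and CGA under 8 alternatives, among them leaving out vehicle replicate 2 (limma adjusted p = 0.149). The camera adjusted p was 1.82e-05 with the preset correlation, and adjusted p = 0.449 with an estimated correlation. Vehicle means were 7.20 ± 0.34 for ERVW-1, 4.46 ± 0.15 for LGALS13 and 6.19 ± 0.25 for CGA, against array medians of 6.83 to 6.87. Vehicle replicate 2, the array that stood apart, read dim probe sets higher than the other vehicle arrays, by a median of up to 0.115, and without it the camera adjusted p of this list was 0.000119. The HTR8/SVneo line carries extravillous traits, and of 23 extravillous trophoblast markers 3 fell and none rose (4 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.15): PLAC8 fell by 0.51, LAIR2 by 0.47 and SNAI1 by 0.45. HLA-G was at 9.81 ± 0.04 with vehicle and 9.73 ± 0.05 with coumestrol (limma adjusted p = 0.539).

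Cytotrophoblast and trophoblast lineage markers split, with 4 of 24 higher and 5 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.555). The transcription factors MSX2 and TFAP2C rose 2.11-fold and 2.02-fold, and the TEAD cofactor VGLL1 was 2.31-fold lower. KRT7 was at 8.39 ± 0.12 with vehicle and 8.26 ± 0.05 with coumestrol (limma adjusted p = 0.47). Of 27 mesenchymal and stromal markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.231): SNAI2 rose 1.76-fold and ZEB1 1.28-fold, while the related factor SNAI1 was 1.36-fold lower. VIM was at 11.56 ± 0.09 and 11.68 ± 0.10 (limma adjusted p = 0.258). Of 22 endothelial and immune markers, 3 fell and none rose (3 fell adjusted over the list alone; camera adjusted p = 0.15), namely PECAM1, CD68 and NKG7.

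**Figure D3:**
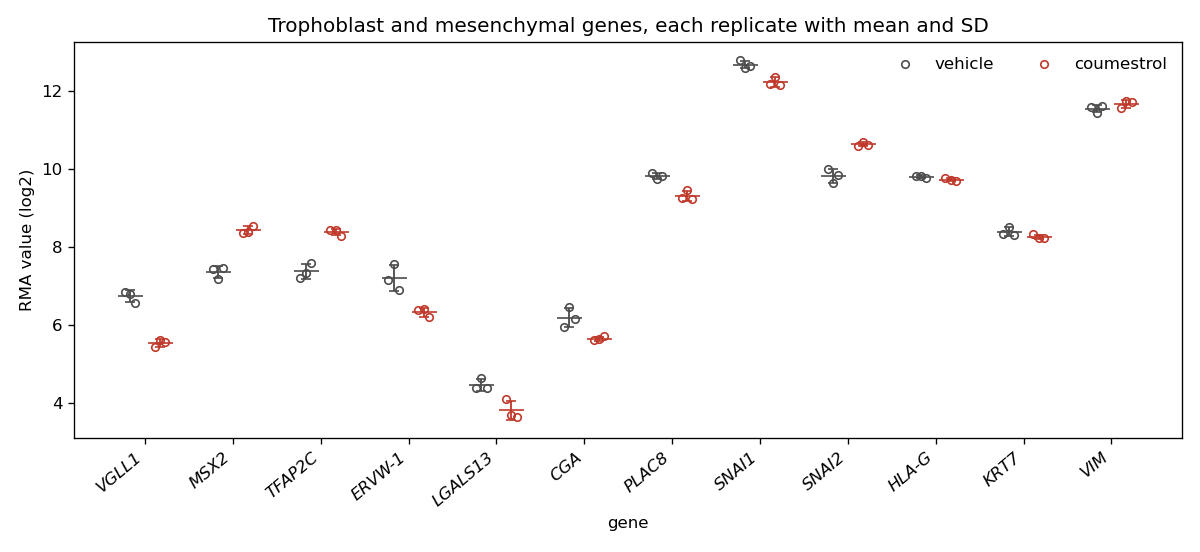
RMA values (log2, vertical axis) of 12 trophoblast and mesenchymal genes, with open circles for the 3 vehicle and 3 coumestrol replicates, horizontal bars for means and whiskers for the SD. MSX2 and TFAP2C lie higher with coumestrol and VGLL1 lower, while the means of HLA-G, 9.81 and 9.73, lie close together.

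Among lists of signalling, angiogenic, hypoxia and inflammatory genes, some had calls in both directions and others in a single direction. Of 21 TGF-beta response genes, 6 rose and 1 fell (7 and 3 adjusted over the list alone), led by the pathway inhibitors SMAD7 (2.0-fold), BAMBI (1.94-fold) and SMAD6 (1.38-fold), with the ligand TGFB1 falling by 0.25. Its camera adjusted p was 0.0465, and adjusted p = 0.602 with an estimated correlation; it was 0.177 without vehicle replicate 2, 0.0962 without coumestrol replicate 2, 0.117 and 0.248 without the dimmest 30% and 50%, 0.261 after another quantile normalization, 0.257 after cyclic loess, 0.0555 with ribosomal protein genes as the reference and 0.0771 with array weights. With the replicate number as a block the camera adjusted p was 0.061. The list's median of 0.12 lay within the central 95% range of random lists of like intensity (-0.097 to 0.154), and was 0.074 without vehicle replicate 2 and 0.07 without coumestrol replicate 3. Of 22 angiogenic factors and receptors, 4 rose and none fell (5 adjusted over the list alone; camera adjusted p = 0.302), with VEGFA up 1.66-fold, placental growth factor PGF 1.38-fold and EFNB2 1.36-fold. Of 28 hypoxia and glycolysis genes, 8 rose and none fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0721), including KDM3A (1.83-fold) and EGLN1 (1.65-fold). Of 26 immediate early and ERK feedback genes, 4 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.335): the phosphatase DUSP1 rose by 0.55, and the transcription factors FOS and EGR1 fell by 0.61 and 0.52. Of 25 NF-kB target genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.656), with the prostaglandin synthase PTGS2 up 1.68-fold and TNFAIP3 up 1.41-fold, and IL24 falling by 0.54. IRF1 fell by 0.38 as the 1 called gene among 29 interferon-stimulated genes (0 adjusted over the list alone; camera adjusted p = 0.39).

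Of 23 invasion proteases and inhibitors, 2 rose (2 adjusted over the list alone; camera adjusted p = 0.941), the protease ADAMTS1 by 1.80-fold and the urokinase receptor PLAUR by 1.57-fold. MMP2 was at 8.52 ± 0.10 with vehicle and 8.38 ± 0.07 with coumestrol (limma adjusted p = 0.364), and MMP9 at 7.10 ± 0.22 and 6.71 ± 0.05 (0.0891). ITGA6 and FN1 were the 2 of 21 integrin and basement membrane genes that rose (2 adjusted over the list alone; camera adjusted p = 0.127), and GADD45B the 1 of 19 YAP and TEAD targets (1 adjusted over the list alone; camera adjusted p = 0.201). In lipid metabolism, 5 of 20 cholesterol genes rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.146), with SC5D up 1.67-fold, HMGCS1 1.40-fold, SQLE 1.31-fold and DHCR7 falling by 0.28, and ACSL1, up 1.79-fold, was the 1 of 13 fatty acid synthesis genes that rose (1 adjusted over the list alone; camera adjusted p = 0.324). Of 27 cytosolic ribosomal protein genes, limma called 0, with 3 at an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.688); RPL10A, at 11.20 ± 0.01 and 11.05 ± 0.06, had an adjusted p of 0.126. NOP16 rose by 0.43 as the 1 of 19 ribosome biogenesis genes called (1 adjusted over the list alone; camera adjusted p = 0.237), and CYC1 fell by 0.28 as the 1 of 29 respiratory chain genes called (1 adjusted over the list alone; camera adjusted p = 0.868).

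In all, 7 of the 34 lists passed the preset camera test, 6 upward and 1 downward. With an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05, the p53 and syncytiotrophoblast lists. Limma's fry asks whether a list's genes move one way on balance and, unlike camera, does not compare them with other genes. It passed 8 lists, among them the angiogenic (fry adjusted p = 0.000234) and ATF4 (fry adjusted p = 0.0229) lists. The heat shock list did not pass (fry adjusted p = 0.0787). For change in either direction, fry passed 32 lists. With 10.7% of all probe sets called, a pass by fry does not set a list apart from other genes. Without vehicle replicate 1 the preset test passed 11 lists, and without the dimmest 30% and 50% of probe sets it passed 3 and 2.

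Of 113 called genes named by the rule, 37 lost their call at the threshold of 0.05 under at least 1 alternative that moderated the variance. For 8 of them this was only with the prior that ignored intensity: TOP2A, DNAJA1, HMGCS1, SQLE, MCM5, EXO1, H3C8 and CDKN1A. Among the other 29, those of stress, metabolism and the estrogen list were ABCC3, XBP1, RARA, MYC, DDIT4, SHMT2, HSPB1, DHCR7, ATG14, SQSTM1, NOP16 and CYC1. Those of the cell cycle, histones and apoptosis were SLBP, BLM, H1-2, H1-4, TNFRSF10B and BCL2L1. The rest were IRF1, IL24, ITGA6, FN1, LAIR2, LGALS13, CGA, ZEB1, NKG7, TGFB1 and GADD45B.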

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

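Cyclic loess and counting identical probe sets once were chosen after the data were seen; the other alternatives were fixed before. Counts of changed probe sets rested most on the variance estimate: against 2302 calls (1616 higher, 686 lower), a prior without an intensity trend gave 1313 (960 and 353), and no moderation gave 184 (149 and 35), with 18 of at least 2-fold against 76, a fit with fewer degrees of freedom per probe set by construction. A threshold of 0.01 left 1094 (879 and 215), as a stricter threshold must. The cause was not tested for the other shifts: lower calls rose to 1070 after another quantile normalization, 1132 with ribosomal protein genes as the reference and 1033 after cyclic loess. The interquartile range of every coumestrol array was above that of every vehicle array, and quantile normalization removes such a difference by construction. Whether that difference came from the treatment was not tested. Centring on ribosomal protein genes moved the median of all probe sets from -0.034 to -0.086. Leaving out 1 array gave 1098 to 2357 calls, 859 to 1659 higher, 239 to 698 lower and 58 to 115 of at least 2-fold; each such fit also holds fewer arrays.

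Samples with the same number did not deviate together, with correlations of -0.261, -0.138 and 0.093. So few arrays cannot show whether the numbers pair the cultures. With the replicate block there were 1686 calls, 1266 higher and 420 lower, and 5 lists, the heat shock and TGF-beta lists having lost their call. The replicate block has 2 fewer residual degrees of freedom.

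Against 7 lists, 3 and 2 passed without the dimmest 30% and 50% of probe sets, 4 after another quantile normalization, 4 after cyclic loess, 0 with an estimated correlation, which by construction counts the correlation between a list's genes, and 5 to 11 with 1 array left out; the cause of the other shifts was not tested. The G2/M and syncytiotrophoblast lists passed under each alternative but the estimated correlation. Of 113 called genes named by the rule, 76 passed at 0.05 under every alternative that moderated the variance and kept the gene, 37 did not, and 0 changed sign under any. The 24 genes with the largest changes lost their call in 18 cases, all without moderation. Signal over background is not known for these values, so dim probe sets limit what small changes could be seen.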

Other observations

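The tests in this part were chosen after the results they address had been seen, except the camera tests of the syncytiotrophoblast list under other settings, of which cyclic loess alone was added later. The count of 40 neighbouring pairs without vehicle replicate 2 was planned before that count was seen. It uses arrays in which neighbouring falls had already been seen, so it is not an independent test. Genes named ZNF, the symbol given to many zinc finger genes, were more often higher than other genes. Of 492 probe sets whose symbol begins with ZNF and a digit (480 of protein-coding genes, 8 of non-coding transcripts and 4 of pseudogenes), 106 (21.5%) rose and 5 fell, against 7.74% higher among the other named probe sets (odds ratio 3.27, two-sided Fisher exact p = 4.42e-21 across probe sets, which are not independent). The median change was 0.14 and the camera adjusted p was 9.7e-11, and adjusted p = 0.00942 with an estimated correlation, adjusted over the 3 families tested. The rises were led by ZNF567 and ZNF302, and the 5 that fell, named after their values were seen, were ZNF135, ZNF438, ZNF672, ZNF584 and the non-coding transcript ZNF582-DT. Among the 480 alone, 105 rose and 4 fell, the median was 0.146 and the camera adjusted p was 5.84e-11, and adjusted p = 0.00921 with an estimated correlation. Higher calls among all 492 numbered 109 after another quantile normalization, 115 after cyclic loess and 86 without vehicle replicate 2.

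The USP17L family moved the other way, with 11 of 14 probe sets lower and 0 higher by limma, a median of -1.24 (2.37-fold) and changes between -1.60 and -0.41 (camera adjusted p = 3.69e-13, and adjusted p = 0.0729 with an estimated correlation). There were 11 lower calls, too, after another quantile normalization, after cyclic loess and without vehicle replicate 2, where the median was -1.12. Olfactory receptor genes, most of them single-exon and silent outside the nose, had 19 of 349 probe sets lower and a median of -0.15 (camera adjusted p = 7.63e-08, and adjusted p = 0.304 with an estimated correlation). Without vehicle replicate 2, 5 were lower, with a median of -0.09. After another quantile normalization 13 were lower and 1 higher, with a median of -0.087. After cyclic loess 14 were lower and 1 higher, with a median of -0.075.

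Of the other lists that passed the preset camera test, the medians of the G2/M (0.254), autophagy (0.17), p53 (0.164) and heat shock (0.141) lists lay above the central 95% range of 10000 random lists of like intensity, with upper bounds of 0.118, 0.130, 0.120 and 0.126. Those of the endoplasmic reticulum (0.129) and TGF-beta (0.117) lists lay inside it, with upper bounds of 0.149 and 0.154. None of these random lists was matched on gene span.

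The change varied with intensity and gene span across all genes. The median log2 change was -0.06 in the dimmest 10% of probe sets, -0.11 in the 20% above them and between 0.02 and 0.04 in the brightest 30%. Calls also depended on intensity. Of 2145 probe sets in the dimmest 10%, limma called 4 higher and 17 lower, and of 2145 in the brightest 10% it called 386 and 144. The number of called genes in a list therefore depends on how bright its genes are. Vehicle replicate 2 minus the other vehicle arrays ran the opposite way, from 0.115 in a dim 10% bin to -0.094 in a bright one. By gene span, the median change was -0.10 in the 20% with the shortest genes and 0.025 in the 20% with the longest, and the share of lower calls went from 5.17% to 1.19%. The share of higher calls was 2.82% in the 20% with the shortest genes, 12.6% in the 20% next to the longest and 8.84% in the longest.

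The lower syncytiotrophoblast markers were set against the drift with intensity, and not against that with gene span. Their median of -0.28 lay below the central 95% range of 10000 random lists of like intensity (lower bound -0.149), with a difference of -0.129, which argues against a shift of dim probe sets as the whole cause. Without vehicle replicate 2 the camera adjusted p was 0.000119, in a range of 1.07e-05 to 0.449 over the alternatives, and the median of -0.248 lay below the range of its random lists (lower bound -0.123), which argues against that array alone. Coumestrol, the biological difference of the design, may lower these genes, which stays a hypothesis. Correlation between the list's genes stays open, since the call was lost with an estimated correlation. The preset camera adjusted p lay under 0.05 in 4 of the 10 splits of the arrays, the real one included. The other splits keep part of the group difference, so these p-values cannot tell correlation from a response. The median, 0.278 in size in the real split, was at most 0.140 in the others.

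The ZNF set was compared with random lists matched on intensity and gene span. Their median lay 0.157 above the central 95% range of those lists, and 0.169 above it without vehicle replicate 2, which argues against a shift with intensity and gene length and against that array alone as the whole cause. For the protein-coding genes alone the differences were 0.157 and 0.168. A response of these genes to coumestrol may be a candidate explanation. In 9 of the 10 splits of the arrays, the real one included, the family's camera p lay under 0.05, so that p does not set the real split apart. The other splits keep part of the group difference, so their p-values cannot tell correlation from a response either. The median of 0.144 in the real split was the highest, with 0.078 next.

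The median of the USP17L probe sets differed by -1.071 from the lower bound of the central 95% range of random lists of like intensity, which argues against a shift with intensity. Their deviations from the group means had a median correlation of 0.865, above the central 95% range (upper bound 0.295) of random lists of lower probe sets, so the 11 probe sets may read one shared pool of transcripts and count as a single observation. Genomic DNA in the RNA may also contribute: the median of olfactory receptor genes differed by -0.060 from the lower bound of random lists of like intensity, as DNA carried over in the vehicle cultures could give, and without vehicle replicate 2 it was -0.088 against a bound of -0.054. The random lists did not count correlation between the olfactory receptor genes, and that family's camera adjusted p was 0.304 with an estimated correlation. No outcome of this comparison could have argued against genomic DNA, and it was not repeated after further normalization. A fall of USP17L transcripts with coumestrol stays open beside a shared pool and genomic DNA.

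Neighbouring genes were examined after several of the largest falls were seen to lie side by side. Of 17249 protein-coding genes in the order of the GRCh38.p14 table, 33 adjacent pairs whose symbols differ before any digit had both genes lower, against a median of 20 and an upper 95% bound of 29 in 10000 permutations within strata of intensity, gene span and local gene density (one-sided permutation p = 0.004). Without vehicle replicate 2 there were 40 pairs, against an upper bound of 25 in 2000 permutations (one-sided permutation p = 0.0005, the smallest they can give). That count rests on arrays already used for the first count and is not independent of it. That filter left in some relatives, such as ITGAX with ITGAD; without pairs that share the starting 3 letters there were 32 pairs against a bound of 29 (one-sided permutation p = 0.0071), and 39 against 25 without vehicle replicate 2. Examples, chosen after their values were seen, were HSF5 with RNF43, PECAM1 with MILR1, and ASB14 with DNAH12. Higher calls made 198 pairs against a bound of 173 with all arrays, and 104 against 105 without vehicle replicate 2. What the paired genes share was not tested.

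With 10 splits of the arrays into 3 and 3, no share under 0.05 can be reached. The splits other than the real one mix vehicle and coumestrol arrays unequally, so part of the group difference stays between their sides. It also widens the spread within each side, which lowers the number of calls. These splits are therefore not free of a treatment response. The real split alone gave its counts of changed, higher, lower and 2-fold probe sets (1 of 10 splits each; 2302, 1616, 686 and 76), with 0 calls by limma in each of the others and 268 to 1931 probe sets at an unadjusted p under 0.05, against 5365. For gene lists, 3 of the 10 splits gave as many as the real 7, with 10 the highest of the others. The median of the G2/M list was 0.254 in the real split and at most 0.195 in the others, though its camera adjusted p lay under 0.05 in 6 of the 10, the real one included. The heat shock list had a median of 0.141 in size in the real split and a larger one, 0.161, in another split.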
